A study of Mus musculus with 25 samples.

How the data were processed

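Bulk RNA-seq was analysed from 25 libraries of sorted mouse cells, 12 from lung and 13 from skin, each sorted as macrophages or as fibroblasts. Per the labels' protocols, lung interstitial macrophages were sorted as live CD45-positive, CD68-positive, F4/80-positive, CD11c-negative and CD11b-high cells. Skin macrophages were sorted as CD45, CD11b, CD68 and F4/80 positive cells, and fibroblasts as PDGFRA-positive cells lacking CD45, CD31 and EPCAM, with CD90 in addition in skin. Libraries were made with a single-cell RNA-seq kit and sequenced as single-end reads. Per the submitters' processing notes, CASAVA 1.8, cutadapt 1.7.1, RSEM 1.7.1 and limma 3.46 were used with the mm10 genome build; the notes give these names with no role or order, and the gene filter and the normalisation method are not given in the sources used here.

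The authors deposited 1 table of normalised values for lung and 1 for skin, whose unit is treated here as a linear signal per gene and library. Within each library the deposited signal equals the estimated read number plus 0.5, multiplied by a constant, so the lowest value of a library stands for 0 reads and the estimated reads can be recovered from it. Values came out as whole reads, within a tolerance of 0.01, for 70.0 to 82.2% of genes per lung library and 27.4 to 58.0% per skin library. The recovered values are therefore estimates and not counts, and count models were not used. In lung, 11.0 to 25.5% of genes per library were at 0 reads, and in skin 1.89 to 22.2%. The tables were normalised separately, so tests were made within a table only.

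Groups were taken from the genotype and cell type labels. Gene identifiers were matched to symbols for 11829 genes in lung and 12641 in skin, with 38 and 20 unmatched, and coordinates come from the GENCODE annotation, release M21, of GRCm38. The tests and groups, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each comparison of depleted with control samples was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided) on log2 of the deposited signal plus a pseudocount of 1 part in 1000000 of the mean library total, which was 1.04 in lung and 1.001 in skin. Fold changes are on this scale, which understates the change of low genes. Genes entered a test with at least 1 part in 1000000 of the library total in at least as many libraries as the smaller group held, a filter that removed no gene in lung. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Numbers of genes at an unadjusted p below 0.05 come from this fit with a variance trend. Without any effect, a share of about 0.05 of the genes tested is expected there. The difference between the effects in macrophages and fibroblasts of an organ was tested as an interaction in a model of 4 groups.

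In all, 40 gene lists were written beforehand, covering macrophage and fibroblast programmes, inflammation, matrix, metabolism, handling and RNA quality, and markers of other cell types that a gate could let through. A list was tested where at least 5 members were measured, with camera (limma) at its preset correlation of 0.01 and adjustment over the lists of that comparison; an estimated correlation and fry were alternatives. The genes named per comparison are the 10 with the lowest p called in each direction, filled up to 5 by lowest p where fewer than 5 passed, up to 4 members of each described list with the lowest p, the gate genes, S100a8, S100a9 and Ly6g, and the 5 with the lowest p in each direction of an interaction; predicted genes were passed over, and 1 gene that the rule names is not reported here. Cell type labels were examined with an exact permutation test of the identity score.

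The fitting steps were tested on simulated data with known changes. With 11867 genes, 76% of 4-fold and 15% of 2-fold changes were recovered for lung macrophages and 71% and 24% for lung fibroblasts. The figures were 100% and 32% for skin macrophages, over 11404 genes, and 84% and 6% for skin fibroblasts, over 12074 genes. Only well-expressed genes were changed, and all genes of a comparison had a common spread between replicates. For skin macrophages the means and the spread came from the depleted libraries alone, and every library was simulated as macrophages. Those figures therefore do not hold for the real comparison, where 2 control libraries have a fibroblast profile. Where all libraries of a group had 0 estimated reads of a named gene, a fold is given as a lower bound against a floor of 3 reads over the group. With 1 to 3 reads the ratio has an exact 95% Clopper-Pearson interval computed from the estimated reads, which covers counting error only. Alternatives covered pseudocounts, filters, scaling, variance models, library weights, a model of 4 groups, replicate number as a block, thresholds and leaving out each library. Added after the data were seen were voom, a filter on estimated reads, no further pseudocount, the sex read from transcripts, and leaving out the 2 skin libraries with a fibroblast profile or the 2 skin fibroblast libraries that stand apart. Replicates of a group were compared on their estimated reads, and none agreed within sampling noise (chi-square per degree of freedom 1.95 to 6.69 in lung and 65.5 to 1133 in skin). Figures were drawn with matplotlib 3.10.9.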

Results

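RNA was measured in macrophages and fibroblasts sorted from the lung and the skin of C57BL/6 mice, with or without depletion of neutrophils. In the depleted mice Cre recombinase, driven by the promoter of S100a8, acts on a diphtheria toxin receptor allele, and S100a8 is expressed chiefly in neutrophils. The control mice are labelled as wild type for Cre. All mice received diphtheria toxin at 10 µg per kg for 7 days, so the control groups were exposed to the toxin as well. The lung libraries form 4 groups of 3, which are depleted and control macrophages and depleted and control fibroblasts. The skin libraries comprise 4 depleted and 3 control macrophage libraries and 3 depleted and 3 control fibroblast libraries. The lung table held 11867 genes and its libraries 124075 to 385925 estimated reads. The skin table held 12661 genes and its libraries 6553115 to 27259903 estimated reads. A single read was therefore worth 2.997 to 6.81 units of the normalised value in lung and 0.0371 to 0.162 in skin. Nothing in the labels says whether the replicates are separate animals. In lung the p-values measure only the spread between these samples, which may be technical. In skin, transcripts of both sexes in each group show at least 2 animals per group.

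The cell type labels were examined first, with a score that subtracts the mean log2 value of 16 fibroblast genes from that of 16 macrophage genes. In lung, macrophage libraries scored 6.56 ± 0.297 (SD, n = 6) and fibroblast libraries −4.73 ± 0.534 (SD, n = 6). The difference was 11.29 (exact two-sided permutation test, p = 0.00216, the smallest that 924 splits can give). In skin, fibroblast libraries scored −9.62 ± 0.409 (SD, n = 6), and 5 of the 7 macrophage libraries scored between 3.71 and 6.16. The library labelled control macrophages 1 scored −9.65 and the library labelled control macrophages 5 scored −10.1, inside the range of the fibroblast libraries. Ptprc, which encodes the leukocyte antigen CD45 used in the macrophage gate, stood at 0.277 and 0.209 in these 2 libraries. It stood at 362 in control macrophages 3 and at 522 to 878 in the depleted macrophage libraries. Cd68, a macrophage lysosomal glycoprotein also used in the gate, stood at 0.390 and 0.905 against 1887 in control macrophages 3. Conversely, Col1a1, a chain of type I collagen, stood at 15309 and 28883 against 267. The title of the library labelled control macrophages 5 contains MFIBRO, while its cell type field says macrophages. With all 13 skin libraries as labelled, the difference between the cell types was 10.24 (exact two-sided permutation test, p = 0.0175). Without those 2 libraries, an alternative chosen after seeing the data, it was 14.44 (exact two-sided permutation test, p = 0.00216).

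**Figure D1:**
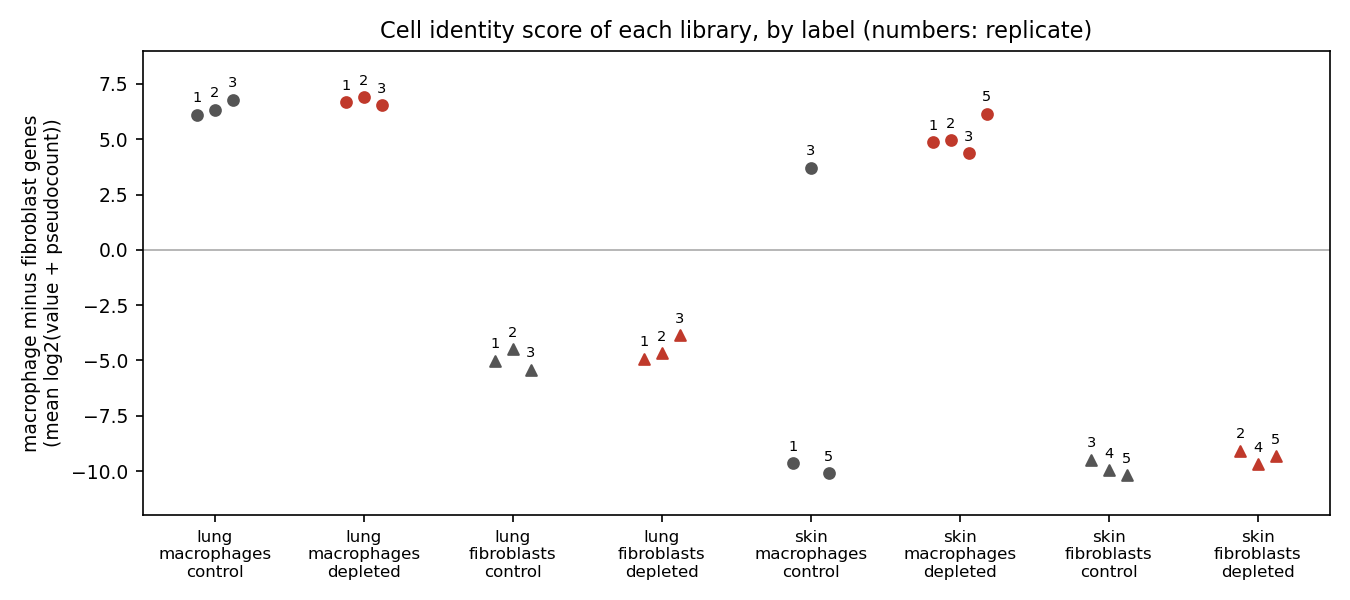
Cell identity score of each library (mean log2 value of macrophage genes minus that of fibroblast genes, vertical axis) by labelled group, with circles for macrophage labels, triangles for fibroblast labels, grey for control and red for depleted mice, and replicate numbers above the points. The libraries labelled control macrophages 1 and 5 of the skin lie at −9.65 and −10.1, among the skin fibroblast libraries, and all other macrophage libraries lie above 0.

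In lung macrophages, the comparison asks how gene expression differs when neutrophils are depleted. Transcripts typical of neutrophils fell. S100a8 (ENSMUSG00000056054, GRCm38 chromosome 3, 90668978 to 90670035), a calcium-binding alarmin abundant in neutrophils, fell by 2.51 ± 0.29 on the log2 scale (SE, adjusted p = 6.68e-08). Its mean was 6517 ± 3653 in control and 1041 ± 140 in depleted mice (SD, n = 3 each). Its partner S100a9 fell by 2.50 ± 0.26 (SE, adjusted p = 5.12e-09). Retnlg (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496), a resistin-like gene of granulocytes, had the lowest p. It fell from 2952 ± 491 to 417 ± 50.7 (SD, n = 3 each, log2 fold change −2.81 ± 0.24, adjusted p = 8.78e-11). Conversely, Retnla, a marker of alternatively activated macrophages, rose from 1727 ± 415 to 3741 ± 364 (SD, n = 3 each, adjusted p = 0.0181). Lyz1, a lysozyme gene, rose from 167 ± 34.1 to 452 ± 11.6 (SD, n = 3 each, adjusted p = 0.00113). Lyz1 is a near-identical neighbour of Lyz2, so the split of reads between them is uncertain. Neither Retnla nor Lyz1 was called without control macrophages 2 (1.14 and 1.30) or 3 (0.97 and 1.44), and Retnla was not without depleted macrophages 2 (1.06) or 3 (1.16). Lyz2 had a log2 fold change of 1.09 and was not called (adjusted p = 0.356).

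In all, 59 of 11867 genes passed an adjusted p of 0.05, with 8 higher and 51 lower in depleted mice. Their absolute log2 fold changes ran from 1.04 to 4.20. Among the lower genes were inflammatory mediators. Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase of prostaglandin synthesis, fell by 4.20 ± 0.39 (SE, adjusted p = 4.91e-10), from 347 ± 68.8 to 19.4 ± 9.72 (SD, n = 3 each). G0s2 (ENSMUSG00000009633, chromosome 1, 193272161 to 193273217), an inhibitor of adipose triglyceride lipase, fell by 3.07 ± 0.27 (SE, adjusted p = 9.65e-11). Il1b, which encodes interleukin 1 beta, fell by 2.46 ± 0.25 (SE, adjusted p = 5.12e-09), and Il1r2, its decoy receptor, by 3.22 ± 0.35 (SE, adjusted p = 2.48e-08). Cxcr2, the chemokine receptor that guides neutrophils, fell by 2.94 and the gelatinase gene Mmp9 by 3.64 (adjusted p = 2.79e-06 and 3.44e-06). The protease inhibitor gene Slpi fell by 1.93 and the chemokine gene Cxcl2 by 1.56 (adjusted p = 2.79e-06 and 1.34e-04). The cytokine gene Osm fell by 1.61 and Nfkbiz, a regulator of NF-kappa-B target genes, by 1.55 (adjusted p = 0.0114 and 0.00768). Cxcr2 and Mmp9 were not called without control macrophages 2 (−2.78 and −3.43) or 3 (−2.84 and −3.44), nor Cxcl2 without control macrophages 2 (−1.59). Osm and Nfkbiz were not without control macrophages 1 (−1.57 and −1.29), 2 (−1.71 and −1.58) or 3 (−1.56 and −1.79), nor Osm without depleted macrophages 3 (−1.39). Genes of the sorting gate did not pass the test. Cd68 stood at 1339 in depleted and 1308 in control mice, Adgre1 (F4/80) at 311 and 268, Itgam (CD11b) at 155 and 209, Itgax (CD11c) at 78.0 and 78.4 and Ptprc at 266 and 425 (means, n = 3 each). Ly6g, the standard surface marker of neutrophils, stood at 29.2 ± 12.2 in depleted and 22.0 ± 5.59 in control mice (SD, n = 3 each). These values rest on 13.03 and 14.17 estimated reads per group (log2 fold change 0.34 ± 0.65, SE, adjusted p = 0.923).

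**Figure D2:**
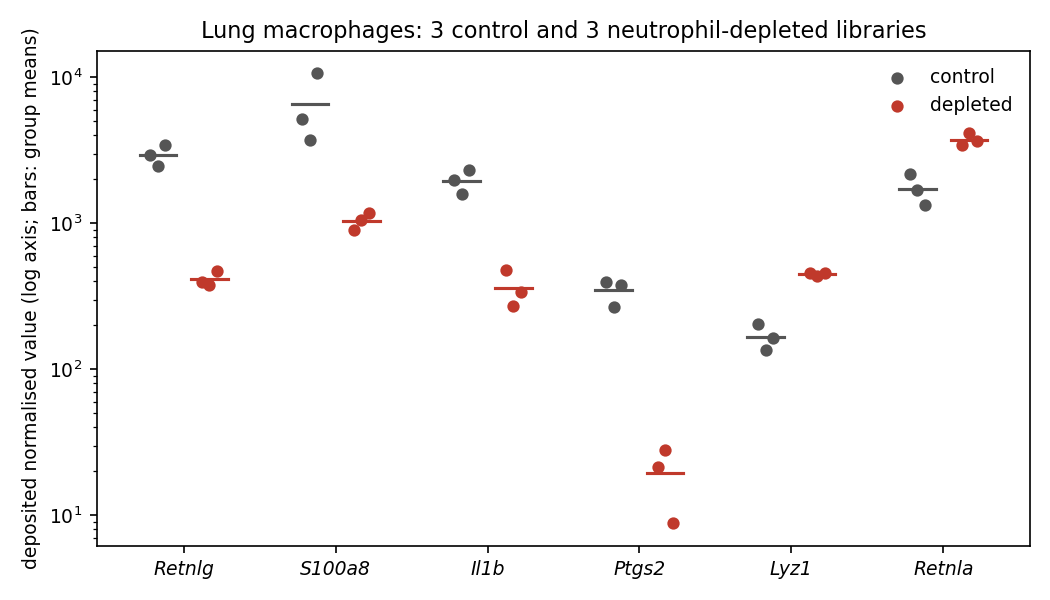
Deposited normalised values of 6 genes in lung macrophages (vertical log axis), with a point per library, grey for the 3 control and red for the 3 depleted libraries, and bars at the group means. Retnlg, S100a8, Il1b and Ptgs2 are lower in all 3 depleted libraries than in any control library, and Lyz1 and Retnla are higher.

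Of the 27 gene lists tested in lung macrophages, 9 were called, 5 higher and 4 lower. The neutrophil list fell, with 12 of 14 members lower, a median log2 fold change of −1.94 and an adjusted p of 6.78e-31. It was the one list called with an estimated correlation (adjusted p = 0.0444 with an estimated correlation). In it 8 genes were called over all genes and 10 when adjusted over the list alone. Its share of all estimated reads was 0.175 ± 0.0181% in depleted and 1.17 ± 0.466% in control libraries (SD, n = 3 each). B and plasma cell genes fell together, with 9 of 9 lower and a median of −1.42 (adjusted p = 1.83e-11, and adjusted p = 0.194 with an estimated correlation). Among them were Igkc, the immunoglobulin kappa constant region, at −2.16 ± 0.41, and Cd79b, part of the B cell receptor, at −2.23 ± 0.52 (SE, adjusted p = 0.00198 and 0.0245). They were not called without control macrophages 2 (−1.99 and −2.35) or 3 (−1.76 and −1.94), nor Cd79b without control macrophages 1 (−2.39) or depleted macrophages 1 (−1.66). Without depleted macrophages 2 Igkc stood at −1.28. In that list 2 genes were called over all genes and 6 when adjusted over the list alone. The inflammatory list, which includes Il1b, Ptgs2, Osm and Nfkbiz, fell with 13 of 19 lower and a median of −0.48 (adjusted p = 2.17e-08, and adjusted p = 0.166 with an estimated correlation). Here 4 genes were called over all genes, and 8 lower and 1 higher when adjusted over the list alone. Immediate-early genes, which cell dissociation can also induce, fell with 17 of 22 lower and a median of −0.27 (adjusted p = 0.00417, and adjusted p = 0.215 with an estimated correlation). None was called over all genes and 1 was when adjusted over the list alone. The median was −0.43 without depleted macrophages 1. Nr4a1 had a log2 fold change of −1.05 and Fosl2 one of −0.82.

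Lung epithelial genes rose in the same macrophage libraries, with 12 of 12 higher and a median log2 fold change of 1.36 (adjusted p = 1.44e-10, and adjusted p = 0.215 with an estimated correlation). The median was 0.77 without control macrophages 3 and 0.78 without depleted macrophages 3, and the list was still called. The surfactant genes Sftpa1 and Sftpd rose by 1.32 ± 0.29 and 2.47 ± 0.61 (SE, adjusted p = 0.0114 and 0.0409). The club cell gene Cyp2f2 rose by 2.06 ± 0.47 and, outside the list, Bpifa1, a secreted airway protein, by 3.63 ± 0.83 (SE, adjusted p = 0.0181 and 0.0198). None of these 4 genes was called without control macrophages 2 (1.66, 2.80, 2.69 and 4.46 in this order), control macrophages 3 (0.83, 1.53, 1.15 and 3.28) or depleted macrophages 3 (1.13, 2.39, 1.46 and 2.34). Without control macrophages 1 Cyp2f2 (2.32) and Bpifa1 (3.14) were not called, and Sftpd was not without depleted macrophages 1 (2.52) or 2 (2.51). In the list 3 genes were called over all genes and 7 when adjusted over the list alone. Its share of reads was 0.943, 1.04 and 2.20% in the depleted and 0.895, 0.816 and 0.206% in the control libraries. Genes of perivascular resident macrophages rose, with 15 of 16 higher and a median of 0.61 (adjusted p = 8.34e-07, and adjusted p = 0.215 with an estimated correlation). The C-type lectin gene Cd209f was called at 1.53 ± 0.37 (SE, adjusted p = 0.0360), whereas F13a1 at 1.05 and Cbr2 at 0.93 were not. Cd209f lost its call without control macrophages 1 (1.36), 2 (2.03) or 3 (1.21) or depleted macrophages 1 (1.41) or 3 (1.41). Over all genes 1 was called, and 5 were when adjusted over the list alone. Genes of MHC class II antigen presentation rose, with 13 of 14 higher and a median of 0.66 (adjusted p = 2.06e-06, and adjusted p = 0.215 with an estimated correlation). None was called over all genes and 5 were when adjusted over the list alone. H2-Ab1 stood at 23249 ± 7710 in depleted and 10027 ± 3065 in control libraries (SD, n = 3 each, log2 fold change 1.21, not called).

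The alternative activation list rose in lung macrophages with 11 of 15 higher and a median of 0.54 (adjusted p = 0.0117, and adjusted p = 0.275 with an estimated correlation). Retnla was called, Clec10a stood at 0.99, and 3 genes were called when adjusted over the list alone. This list was not called without control macrophages 3 (median 0.47) or depleted macrophages 1 (median 0.40), and its median was 0.33 without control macrophages 1. The macrophage identity list rose with 11 of 16 higher and a median of 0.20 (adjusted p = 0.0367, and adjusted p = 0.519 with an estimated correlation). C1qb and C1qc of the complement cascade stood at 0.78 and 0.82. None of its genes was called over all genes, and 4 higher and 1 lower were when adjusted over the list alone. It was not called without control macrophages 1 (median 0.03) or 2 (0.31), without depleted macrophages 1 (0.15) or 3 (0.21), or with either of the other scalings. Its median was 0.37 without control macrophages 3 and 0.32 without depleted macrophages 2. Ctsb, a lysosomal protease gene, was called at 1.34 ± 0.30 (SE, adjusted p = 0.0165). It was not called without control macrophages 1 (1.02), 2 (1.49) or 3 (1.51) or depleted macrophages 1 (1.31) or 2 (1.34). The list of neutrophil recruitment genes had a median of 0.11 but a mean of −0.34 and a test pointing down that was not called (adjusted p = 0.105). Leaving out control macrophages 2 or 3 lowered the number of genes called to 11 and 12. Of 24 called genes examined in this way, 8 were called in every fit that left out 1 library, and all 8 were lower in depleted mice (Retnlg, G0s2, Ptgs2, Il1b, S100a9, Il1r2, S100a8 and Slpi). With quantile normalisation 27 genes were called, of which 1 was higher, and with a 4-group model 18. With limma without a variance trend 0 were, and voom called 58. With the trend, 942 genes (7.94%) had an unadjusted p below 0.05.

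In lung fibroblasts, the question was whether stromal cells of the same organ differ when neutrophils are depleted. Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), a secretory protein of airway club cells, was the one gene of 11867 called. It rose from 216 ± 49.9 to 633 ± 346 (SD, n = 3 each), a log2 fold change of 1.43 ± 0.27 (SE, adjusted p = 0.00671). Sftpc, the surfactant gene of alveolar type 2 cells, stood at 2005 ± 1571 in depleted and 834 ± 578 in control libraries (SD, n = 3 each, log2 fold change 1.36, adjusted p = 0.1197). Its fold change ran from 0.57 to 1.89 in fits without 1 library, and it was called in 3 of the 6. Lung epithelial genes rose as a list, with 10 of 12 higher and a median of 0.89 (adjusted p = 1.22e-04, and adjusted p = 0.777 with an estimated correlation). In it 1 gene was called over all genes and 3 when adjusted over the list alone. Their share of reads was 0.203, 0.232 and 0.578% in the depleted and 0.167, 0.233 and 0.0560% in the control libraries. This list was not called without control fibroblasts 3 (median 0.37).

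Fibrillar and associated collagens fell as a list in lung fibroblasts, with 9 of 12 lower and a median log2 fold change of −0.41 (adjusted p = 0.00489, and adjusted p = 0.777 with an estimated correlation). None was called over all genes and 1 was when adjusted over the list alone. The type VI collagen chains stood at −0.77 for Col6a1, −0.73 for Col6a2 and −0.58 for Col6a3, and the type I chain Col1a2 at −0.46. The fibroblast identity list fell with 12 of 16 lower and a median of −0.24 (adjusted p = 0.00487, and adjusted p = 0.777 with an estimated correlation). None of its genes was called over all genes or when adjusted over the list alone, and the gelatinase gene Mmp2 stood at −0.56. Neither list was called without control fibroblasts 1 (medians −0.39 and −0.12) or without depleted fibroblasts 3 (−0.21 and −0.17), and with quantile normalisation none of the 3 lists was. Pdgfra, the receptor used in the gate, stood at 668 ± 105 in depleted and 688 ± 190 in control libraries (SD, n = 3 each). Pecam1, an endothelial gene whose product CD31 the gate excludes, stood at 201 and 205, and S100a8 at 9.23 and 12.6. Of the other genes the gate excludes, Epcam had 2 and 0 estimated reads and Ptprc 4 and 1.

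Other lung fibroblast genes with low p were not called (adjusted p from 0.357 to 0.611). On the higher side the phospholipase gene Pnpla8 stood at 1.56 and Dnttip2 at 1.67. Bpifa1 had 97 estimated reads over the depleted and 0 over the control libraries, at least 29.7-fold higher against a floor of 3 reads over the group. Its fitted log2 fold change was 3.38, and 1.74 without depleted fibroblasts 2. On the lower side Colgalt1, which adds galactose to collagen, stood at −2.73, Tspan9 at −1.60, Scarf2 at −1.40 and Gapvd1 at −1.55. Pgpep1 had 0 estimated reads over the depleted and 11.03 over the control libraries, at least 4.01-fold lower against the same floor. The call of Scgb1a1 was lost without depleted fibroblasts 3 (1.02, 0 genes called) and without control fibroblasts 3 (1.27, 2 others called). With quantile normalisation, no variance trend, a 4-group model or a filter of 3 reads limma called 0 genes, and voom called 4. With the trend, 600 genes (5.06%) had an unadjusted p below 0.05. Without control fibroblasts 1, control fibroblasts 2 and depleted fibroblasts 2, 5, 6 and 7 genes were called.

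**Figure D3:**
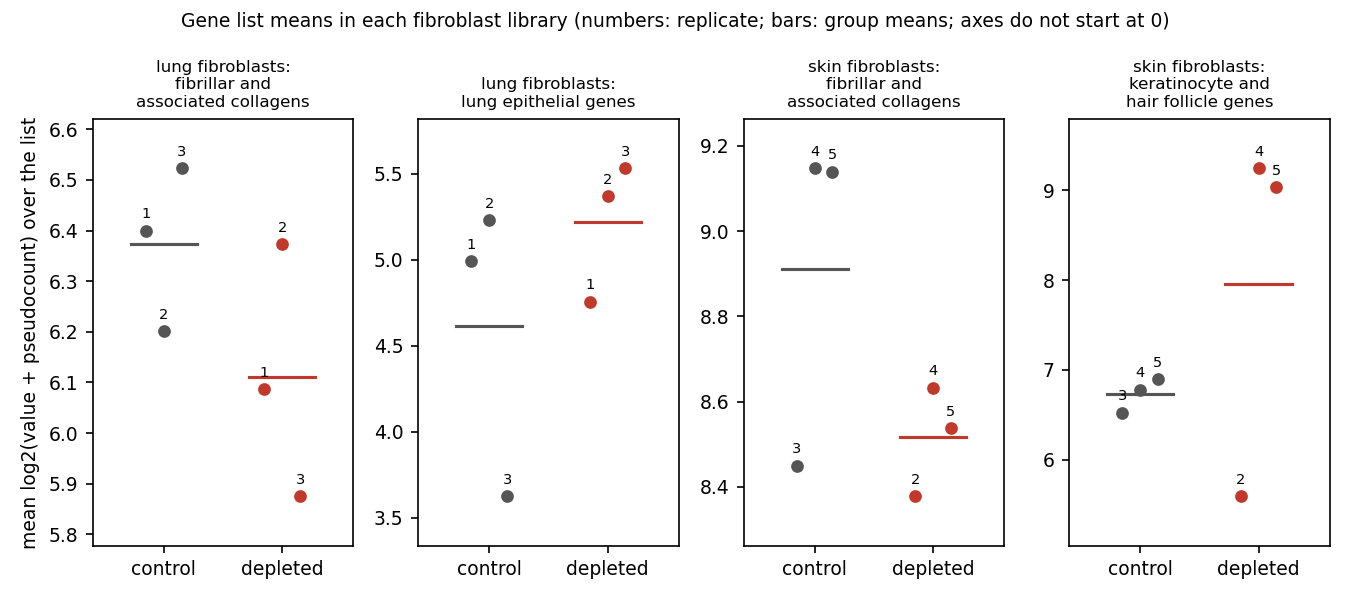
Mean log2 value of a gene list in each fibroblast library (vertical axes, which do not start at 0), with grey points for control and red for depleted libraries, replicate numbers above the points and bars at the group means. The left panels show collagens and lung epithelial genes in lung, and the right panels collagens and keratinocyte genes in skin, where depleted fibroblasts 4 and 5 lie at 9.24 and 9.03 for keratinocyte genes and all other libraries at 6.90 or below.

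The difference between the depletion effects in lung macrophages and in lung fibroblasts was tested directly. The effect was more negative in macrophages for G0s2, with a difference of −3.27 ± 0.41 on the log2 scale (SE, adjusted p = 9.75e-05). In fibroblasts G0s2 had 293 estimated reads over the depleted and 211 over the control libraries. The effect was also more negative in macrophages for Ptgs2, with −4.90 ± 0.85 (SE, adjusted p = 0.0175), where the fibroblast groups held 4 and 1 estimated reads. These were the 2 genes called of 11867. Next came Retnlg at −2.75 and Cxcr2 at −3.46 (adjusted p = 0.0980 for both) and the kinase gene Stk17b at −2.80 (adjusted p = 0.108), none of them called, and Retnlg had 0 estimated reads in both fibroblast groups. On the positive side, the zinc finger gene Zfp429 stood at 3.41, the purine salvage gene Aprt at 2.02, Sirt4 at 3.85, Pgpep1 at 3.51 and Srxn1 at 3.66, also not called. Of these, all but Aprt had at least 1 group with 0 to 2 estimated reads. G0s2 was called in each of the 12 fits without 1 library and Ptgs2 in 7. Ptgs2 was not called without control macrophages 1 (−4.79), 2 (−5.07) or 3 (−4.83), depleted macrophages 3 (−4.44) or depleted fibroblasts 3 (−4.48). The count was 1 gene in those fits other than the one without control macrophages 2, and 6 without depleted fibroblasts 2. With limma without a variance trend 0 genes were called, and voom called 1. With the trend, 653 of 11867 genes had an unadjusted p below 0.05.

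In skin fibroblasts, genes of the collagen matrix were lower in depleted mice as lists, while no single gene was called. Fibrillar and associated collagens fell, with 12 of 15 lower and a median log2 fold change of −0.58 (adjusted p = 2.62e-05, and adjusted p = 0.690 with an estimated correlation). Col1a1, of type I collagen, stood at 11090 ± 2535 in depleted and 21342 ± 5978 in control libraries (SD, n = 3 each, log2 fold change −0.93). Col1a2 (chromosome 6, 4504814 to 4541544), its partner chain, stood at 8691 ± 1475 and 17352 ± 1463 (SD, n = 3 each, log2 fold change −1.01). The type V chains Col5a1 and Col5a2 stood at −0.74 and −0.65, Col12a1 at −0.71 and Col16a1 at −1.07. Elastic fibre and matrix glycoprotein genes fell with 25 of 27 lower and a median of −0.39 (adjusted p = 3.11e-05, and adjusted p = 0.690 with an estimated correlation), among them the microfibril gene Mfap2 at −0.61. The median was −0.16 without depleted fibroblasts 4, and the list was still called. The fibroblast identity list fell with 14 of 16 lower and a median of −0.44 (adjusted p = 9.21e-04, and adjusted p = 0.690 with an estimated correlation). It was not called without control fibroblasts 4 (median −0.45) or 5 (−0.34), or with quantile normalisation. Collagen processing genes fell with 15 of 21 lower and a median of −0.25 (adjusted p = 0.0154, and adjusted p = 0.690 with an estimated correlation). They included the crosslinking enzyme gene Loxl2 at −0.68 and Crtap, part of the prolyl 3-hydroxylation complex, at −0.85. This list was not called without control fibroblasts 4 (median −0.02) or 5 (−0.16) or depleted fibroblasts 4 (−0.13), and its median was −0.53 without control fibroblasts 3.

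Keratinocyte and hair follicle genes rose in the same skin fibroblast comparison, with 14 of 14 higher and a median of 1.11 (adjusted p = 2.62e-05, and adjusted p = 0.690 with an estimated correlation). The keratin genes Krt1 and Krt17 stood at 2.39 and 1.78, Sfn at 2.23 and Trp63, a transcription factor of basal keratinocytes, at 1.27. In fits without 1 library Krt1 ran from 1.63 to 3.66, Krt17 from 1.07 to 2.27, Sfn from 1.29 to 3.67 and Trp63 from 0.75 to 2.11. The share of reads of the list was 0.154, 2.09 and 1.81% in depleted fibroblasts 2, 4 and 5 and 0.364, 0.497 and 0.474% in control fibroblasts 3, 4 and 5. The list was not called without depleted fibroblasts 4 (median 0.30), nor without depleted fibroblasts 4 and control fibroblasts 3, which stand apart from the rest (0.38). Its median was 2.21 without depleted fibroblasts 2 and 0.63 without depleted fibroblasts 5. Nuclear-encoded respiratory chain genes rose with 20 of 24 higher and a median of 0.20 (adjusted p = 0.0371, and adjusted p = 0.690 with an estimated correlation), with Sdhd at 0.73 and Uqcrc1 at 0.63. They were not called without control fibroblasts 4 (median 0.14) or 5 (0.11), without depleted fibroblasts 2 (0.20) or 4 (0.10), or with median-of-ratios scaling. Their median was 0.34 without depleted fibroblasts 5 and 0.35 without control fibroblasts 3. No gene of these 6 lists, out of 24 tested, was called over all genes or when adjusted over the list alone. The gate genes Pdgfra and Thy1 stood at 287 ± 73.4 and 164 ± 60.2 in depleted and 398 ± 52.4 and 231 ± 30.5 in control libraries (SD, n = 3 each). Epcam, whose product the gate excludes, stood at 3.93, 42.4 and 24.1 in depleted fibroblasts 2, 4 and 5. In control fibroblasts 3, 4 and 5 it stood at 0.305, 9.51 and 16.0.

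The skin fibroblast genes with the lowest p were not called (adjusted p = 0.955 for each). On the higher side Tpd52 stood at 2.04, Mall at 3.87, Slc2a12, a glucose transporter, at 3.56, Fibin at 1.88 and Dynlt3 at 0.95. On the lower side Fkbp14, a collagen chaperone, stood at −1.19, Cpz at −1.35, Khdrbs3 at −3.38, Reck, a metalloprotease inhibitor, at −0.98 and Igsf10 at −1.09. Of 11780 genes 0 were called by limma with or without a variance trend and 0 by voom, whereas 16 genes were called without depleted fibroblasts 2. With the trend, 283 genes (2.40%) had an unadjusted p below 0.05. Libraries 4 and 5 alone, which carry Ddx3y of the Y chromosome, gave 47 genes and 13 lists, a choice made after seeing the data. With sex as a covariate, chosen likewise, there were 0 genes and 7 lists. Without control fibroblasts 3, 11 lists were called.

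In skin macrophages as labelled, 4 depleted libraries were compared with 3 control libraries, of which 2 carried a fibroblast profile. Fibroblast identity genes had a median log2 fold change of −4.92 with 16 of 16 lower (adjusted p = 2.69e-12, and adjusted p = 0.317 with an estimated correlation). Macrophage identity genes had one of 6.16 with 15 of 16 higher (adjusted p = 4.59e-09, and adjusted p = 0.317 with an estimated correlation). In all, 19 of 26 lists were called, 12 higher and 7 lower. The genes with the lowest p were not called (adjusted p = 0.0879 for each). On the higher side Pira2 stood at 6.62, Cyp4v3 at 4.24, Tarm1 at 5.11, Tfec at 4.44 and the interferon-induced gene Usp18 at 2.94. On the lower side Ccnd2 stood at −2.34, Angptl1 at −5.96, Rhobtb3 at −4.56 and Galnt15 at −5.64, and Bmp5 had 1.40 estimated reads over the depleted and 3951 over the control libraries. At equal depth that is a ratio of 2206 (95% exact interval 494 to 35585, which covers counting error only). None of 11716 genes was called by limma with a variance trend or by voom, with 2458 at an unadjusted p below 0.05, and 45 were called by limma without a trend. Without control macrophages 3, the one control library with a macrophage profile, 2908 genes were called.

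Without the 2 libraries, a choice made after seeing the data, 4 depleted skin macrophage libraries were compared with control macrophages 3 alone, which was assumed to vary like the depleted libraries. Retnla stood at 390 ± 75.4 (SD, n = 4) in depleted libraries and at 98.4 in the control library (log2 fold change 1.95, adjusted p = 0.445). Ccnd2, a G1 cyclin gene, stood at 78.3 ± 20.0 (SD, n = 4) and 365 (log2 fold change −2.25, adjusted p = 0.445). Cyp4v3 (chromosome 8, 45304944 to 45333216), a fatty acid hydroxylase gene, stood at 84.0 ± 27.1 (SD, n = 4) and 0.975 (log2 fold change 5.36, adjusted p = 0.208). The leukotriene B4 receptor gene Ltb4r1 stood at 129 and 17.7, Pira2 at 316 and 17.3 and Dcps at 47.2 and 0.871. On the lower side Rhobtb3 had a log2 fold change of −3.97, and 3 genes had few reads in depleted libraries. Bmp5 had 1.40 estimated reads over the 4 depleted libraries and 254.91 in the control library, Dab1 had 3 and 287, and the mast cell receptor gene Mrgprb1 had 1.12 and 252.38. At equal depth these are ratios of 557 (95% exact interval 124 to 9019), 292 (99.1 to 1427) and 689 (132 to 19501), intervals that cover counting error only and compare these libraries, not the conditions. S100a8 stood at 10.1 ± 3.22 (SD, n = 4) and 36.4. The gate genes stood at 684 and 362 for Ptprc, 1760 and 1887 for Cd68 and 612 and 453 for Adgre1. No gene of 12028 was called by limma with or without a variance trend or by voom, with 834 at an unadjusted p below 0.05.

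Of 28 lists, 7 were called in this reduced skin macrophage comparison, and each had an adjusted p = 0.615 with an estimated correlation. The control side is control macrophages 3 alone, so these tests hold no spread between controls and compare these libraries, not the conditions. Fell and rose here mean lower and higher than in that library. Mitochondrial genes held 6.49% of its reads, against 2.68 to 4.15% in depleted libraries, and keratinocyte genes 0.658% against 0.153 to 0.364%. Mitochondrially encoded genes fell with 15 of 15 lower and a median of −0.97. Among them, the respiratory complex I genes mt-Nd2 and mt-Nd1 stood at −1.43 and −1.04. Keratinocyte genes fell with 12 of 14 lower and a median of −1.29 (adjusted p = 1.08e-04), with Krt5 at −2.04 and Dsp at −1.42. Fibroblast identity genes fell with 15 of 16 lower and a median of −1.36 (adjusted p = 1.08e-04), with Col1a2 at −1.59 and Col3a1 at −1.45. Mast cell and basophil genes fell with 7 of 7 lower and a median of −3.19 (adjusted p = 5.48e-04). Among them the protease genes Mcpt4 and Cma1 stood at −4.27 and −3.20, and the transcription factor gene Gata2 had 3 estimated reads over the depleted libraries and 174.53 in the control library, a ratio of 178 at equal depth (95% exact counting interval 59.9 to 871). Monocyte genes rose with 11 of 17 higher and a median of 0.52 (adjusted p = 0.0210), among them the chemokine receptor gene Ccr2 at 1.03, Chil3 at 1.53 and Hp at 2.41. Glycolysis and hypoxia genes rose with 13 of 20 higher and a median of 0.25 (adjusted p = 0.0216). Pkm, a pyruvate kinase, stood at 1351 ± 464 (SD, n = 4) and 428, and Eno1 had a log2 fold change of 1.06. Alveolar macrophage genes rose with 7 of 10 higher and a median of 0.86 (adjusted p = 0.0286), or 1.06 with its 2 genes at 0 reads in the control library set to their lower bounds. No gene of these lists was called over all genes, and 1 mast cell gene was when adjusted over the list alone. Without depleted macrophages 1 the monocyte (median 0.80), glycolysis (0.24) and alveolar macrophage (0.47) lists were not called, and without depleted macrophages 3 the number of lists called was 11. The macrophage identity list had a median of −0.11 but a mean of 0.06 and a test pointing up that was not called (adjusted p = 0.741).

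The difference between the depletion effects in skin macrophages and in skin fibroblasts, with the libraries as labelled, was lowest in p for Bmp5 at −6.06 (adjusted p = 0.0670) and Angptl1 at −5.62 (adjusted p = 0.0785). Ccnd2 followed at −2.27, Galnt15 at −5.39 and Col4a2, a basement membrane collagen gene, at −5.49. On the positive side Mob3a stood at 3.22, Esyt1 at 3.13, Dclre1c at 5.27, G6pdx at 2.41 and Ceacam1 at 5.60. The median difference over all genes was −0.22, and 0.01 after median-of-ratios scaling. Of 11013 genes 0 were called by limma with or without a variance trend and 0 by voom, with 1227 at an unadjusted p below 0.05, and 1006 were called without control macrophages 3. Without the 2 libraries 0 of 11220 genes were called by limma or by voom, with 432 at an unadjusted p below 0.05.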

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

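The tests on the skin control libraries, on the neutrophil share of reads and on the B cell list were chosen after the results were seen. The tests of depth, dilution and other splits of the samples were set beforehand. The 2 libraries that stand apart were picked after the data were seen, and only the rule for reading their test was set beforehand.

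The libraries labelled control macrophages 1 and 5 of the skin carried a fibroblast profile. A swap with a library labelled as skin fibroblasts would leave a macrophage profile under a fibroblast label, but the highest score of the 6 such libraries was −9.09. No library of control fibroblasts 1 is among them, and a swap with a library outside these 6 would leave no trace here. Fibroblast RNA mixed into macrophage RNA would leave macrophage transcripts visible, but the median macrophage gene stood at 0.0387% and 0.0595% of its mean in depleted macrophages, against 0.0569 to 0.188% in fibroblast libraries and 95.1% in control macrophages 3. That 2 of the 2 identity scores lay within the range of the fibroblast-labelled libraries is the pattern itself and decides nothing. Over the 12629 genes outside the identity lists, the Spearman correlation with fibroblast-labelled libraries exceeded that with depleted macrophages by 0.338 and 0.358, against 0.261 to 0.349 for fibroblast-labelled libraries and −0.275 for control macrophages 3. Fibroblasts under a macrophage label may therefore be the source. The labels cannot say whether the tube, the sort or the sheet was wrong, and no biological explanation was tested.

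Genes lower in lung macrophages of depleted mice include many that neutrophils express. A smaller share of neutrophil RNA may account for falls no larger than its own: the share of the neutrophil list, led by S100a8 at 6517 and Retnlg at 2952 in controls, differed by −2.74 (SE 0.336) on the log2 scale, and of the 51 lower genes 1, Ptgs2 at −4.20, lay below that by over 2 standard errors of its own fold change. By the rule of this test, 1 such gene is no more than chance gives, and the standard error of the share itself was not counted. It therefore does not set Ptgs2 apart. Ly6g, also of neutrophils, did not share the fall of the neutrophil list, at 0.34 ± 0.65 (SE) on 13.03 and 14.17 estimated reads. The explanation was not enough for the B and plasma cell list, whose median was −1.42, with Igkc at 843 in controls, although neutrophils do not express it; neither list shares a gene with another list, and a gate on F4/80 and CD68 should remove both cell types. Little of the size of these falls came from unequal depth. With every library thinned to 180331 estimated reads, the median change of the lower genes kept 99.96% of its size (96.6 to 102.3% over 10 draws). Thinned values keep their scale, so genes at many reads could hardly move in this test. The number of genes called did fall, to 13 to 19 from 59. A change within the macrophages themselves stays open. That 43 of the lower genes are outside the neutrophil list does not argue for it. The list holds 14 measured genes, and neutrophils may express others.

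Collagen genes were lower as lists in fibroblasts of depleted mice while epithelial or keratinocyte genes were higher. None of these lists was called with an estimated correlation. Dilution by RNA of other cells would lower all fibroblast-specific genes alike. In lung the median of 129 other such genes was 0.0311 (SE 0.0342) against −0.41 for the collagens. This argues against it for these genes but does not exclude it. They were chosen as abundant and far higher in fibroblast than in macrophage libraries, so genes of further cell types may be among them. The fibroblast identity list fell there by a median of −0.24. The collagen mean was lowest, 5.87, in depleted fibroblasts 3, where the epithelial share was highest (0.578%). It was highest, 6.52, in control fibroblasts 3, where that share was lowest (0.0560%). In skin the median of 200 other fibroblast-specific genes was −0.26 (SE 0.0347) against −0.58 for the collagens. This lies between the values that would decide, so dilution and a change in collagen expression cannot be told apart. The most abundant keratinocyte genes there, Krt15 and Krt14, stood at 2540 and 2395 in depleted and 916 and 1043 in control libraries, 1 of the 14 genes of that list is in another list, and the exclusion of EPCAM should remove most such cells. Epcam transcripts were nevertheless present, at 3.93, 42.4 and 24.1 in depleted fibroblasts 2, 4 and 5 and 0.305, 9.51 and 16.0 in control fibroblasts 3, 4 and 5. Depleted fibroblasts 2 had the lowest keratinocyte share, 0.154% against 0.364 to 0.497% in controls. It also had the lowest collagen mean, 8.38 against 8.45 to 9.15. By the sex read from transcripts it is female, and the one female control, control fibroblasts 3, stood at 8.45. In the male libraries, depleted fibroblasts 4 and 5 had collagen means of 8.63 and 8.54 and keratinocyte shares of 2.09 and 1.81%. Control fibroblasts 4 and 5 had means of 9.15 and 9.14 and shares of 0.497 and 0.474%. Within a sex, the larger collagen difference thus lay where the keratinocyte share was higher in depleted mice. These few libraries do not decide on dilution. Without the 2 skin libraries that stand apart, depleted fibroblasts 4 and control fibroblasts 3, the collagen median was −0.57. These had the highest collagen mean of the depleted and the lowest of the control libraries, 8.63 and 8.45. They therefore did not produce the fall, and leaving them out was no test of it. Both control libraries left are male by transcripts. An effect of neutrophil depletion on collagen expression stays open, as a hypothesis found on these data.

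In other splits of the same lung macrophage libraries into 3 and 3, the highest gene count was 3 against the real 59 (1 of 10 splits as large) and the highest list count 8 against 9 (1 of 10). For lung fibroblasts these were 3 against 1 for genes (4 of 10 splits as large) and 5 against 3 for lists (3 of 10), and for skin fibroblasts 9 against 6 for lists (4 of 10). The 10 splits of 3 against 3 are too few for a share under 0.05. For the skin macrophage lists 6 of 35 splits were as large (real 19, highest other 21). There the count followed the 2 libraries with a fibroblast profile. Splits with both on the same side called 15 to 21 lists, and splits that part them 0 to 9. These splits therefore cannot speak to chance. For the lung interaction chance was not excluded, with 10 of 100 splits as large (real 2, highest other 7). Where the real number of genes was 0 every split is as large, so the splits say nothing of chance; these were skin fibroblasts (10 of 10, highest other 0), skin macrophages (35 of 35, highest other 0) and the skin interaction (100 of 100, highest other 1).

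The depletion effect differed between lung macrophages and lung fibroblasts for G0s2, by −3.27, and for Ptgs2, by −4.90, in the test of the difference itself, for which other splits did not exclude chance. The neutrophil list held 1.17 and 0.175% of reads in control and depleted macrophages, and 0.00496 and 0.00580% in control and depleted fibroblasts. For genes that neutrophils express, its smaller share could by itself give such a difference. In macrophages Ptgs2 fell by more than that share, but 1 such gene among the 51 lower ones is no more than chance gives by the rule of that test. The call of G0s2 was lost with no variance trend. That of Ptgs2, where fibroblasts held 4 and 1 estimated reads, was lost in 5 of 12 fits without 1 library: control macrophages 1 (−4.79), 2 (−5.07) and 3 (−4.83), depleted macrophages 3 (−4.44) and depleted fibroblasts 3 (−4.48). It was also lost with quantile normalisation, no trend, voom and no further pseudocount. Among the 4 depleted skin macrophage libraries, 1 library stood far from the other 3 in 4 of the 44 series of values examined, where chance alone gives about 1 in 20. The share of B cell transcripts was 0.0457% in depleted macrophages 1 against 0.0269 to 0.0295%, Galnt15 stood at 1.54 there against 0.181 to 0.372, and Mrgprb1 at 0.262, which is 1.12 estimated reads, against 0.0312 to 0.0355, which are 0 reads. Angptl1 stood at 1.44 in depleted macrophages 5 against 0.243 to 0.267. Depleted macrophages 1 was also the shallowest skin library, at 6553115 estimated reads, where 1 read is worth 0.162.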

How the results depend on the processing

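The settings voom, the filter of 3 estimated reads, no further pseudocount, the sex settings and those without 2 libraries were chosen after the data were seen; all settings of skin macrophages without the 2 libraries were too. Of the gene values recomputed, 2763 of 3000 kept their direction and side of the threshold, 145 became weaker, 85 stronger and 7 moved; of the list results 566 of 701 kept the direction of their test and their call, 129 lost the call and in 6 the test turned direction; of the counts and identity scores 212 of 279 did and 67 moved. Where no reason is given, the cause was not tested. Count models (quasi-likelihood and size-factor tests) were planned only for count tables and not run, since the values are not whole reads.

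In lung macrophages (59 genes, 9 lists), quantile normalisation called 27 genes, the 4-group model 18, no variance trend 0 and fits without 1 library 11 to 70. An estimated correlation and fry left 1 list each, and fits without 1 library 8 to 11. In lung fibroblasts (1 gene, 3 lists), testing the 11587 genes above 0 reads in at least 1 library called 3 genes, voom 4, and quantile normalisation, no trend, the 4-group model and the filter of 3 reads 0, with 0 to 7 without 1 library. Quantile normalisation, an estimated correlation and fry left 0 lists, and fits without 1 library 1 to 4. The lung interaction (2 genes) gave 6 with a pseudocount 5 times as large, 4 at an adjusted p below 0.1, 1 with quantile normalisation, voom, the filter of 3 reads or no further pseudocount, 0 with no trend and 1 to 6 without 1 library.

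In skin macrophages as labelled (0 genes, 19 lists), a pseudocount 5 times as large called 1 gene, no trend 45, library weights 3511, the 4-group model 975, an adjusted p below 0.1 693, and fits without 1 library 0 to 2908. Without the 2 libraries 7 lists were called, with an estimated correlation or fry 0 and without 1 library 18 to 20. Without the 2 libraries list medians reversed to −0.38 for perivascular macrophage, −0.23 for inflammatory, −0.45 for alternative activation −0.11 for macrophage identity, −0.10 for interferon and −0.34 for respiratory chain genes (−0.18 without control macrophages 5 and 0.55 without control macrophages 3), and the test of Langerhans and dendritic cell genes turned down at a median of 0.12. The settings without the 2 libraries or control macrophages 5 remove fibroblast-profile libraries from the control group, and that without control macrophages 3 removes its one macrophage-profile library. Rescaling moved the median of all genes from −0.09 to 0.03 (median of ratios) and 0.05 (quantile), and in the skin interaction from −0.22 to 0.01 and −0.07. In skin macrophages without the 2 libraries (0 genes, 7 lists), quantile normalisation called 2 genes, robust fitting 1 and library weights 13. A filter 5 times as strict and quantile normalisation called 11 lists, fry 1, an estimated correlation 0 and fits without 1 library 5 to 11. The skin interaction (0 genes) gave 1 with a pseudocount 0.1 times as large, quantile normalisation or no further pseudocount, 1501 with library weights, 2 at an adjusted p below 0.1 and 0 to 1006 without 1 library.

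In skin fibroblasts (0 genes, 6 lists), males only gave 47 genes and 13 lists, fits without 1 library 0 to 16 genes and 4 to 11 lists, leaving out the 2 that stand apart 10 lists, and an estimated correlation and fry 0. With replicate number as a block, skin fibroblasts gave 84 genes and 13 lists and lung fibroblasts 4 genes, and no other count moved by over 1.5 times, although macrophage identity in lung macrophages was no longer called (adjusted p = 0.0933). Same-numbered deviations of depleted and control libraries of a cell type correlated by −0.0732 to 0.0846, which gives no sign that the numbers pair them. Macrophage and fibroblast libraries of the same number were not compared in this way, and the interaction treats them as independent. In lung the epithelial share was lowest in control 3 of both cell types (0.206% in macrophages, 0.0560% in fibroblasts). It was highest in depleted 3 of both (2.20 and 0.578%). Such libraries may share a source, so the epithelial rises in the 2 cell types may not be independent. In skin, libraries of the same number share a sex, so the block there also removes differences between the sexes. Of the skin fibroblasts, only numbers 4 and 5 occur in both groups. With this block the effect there rests on those libraries alone, since depleted fibroblasts 2 and control fibroblasts 3 have no counterpart. These counts are not read as effects. The identity difference stayed at 11.15 to 11.47 in lung and 9.32 to 12.03 in skin without 1 library. Depth limits what can be said of lung genes at a few reads, as 1 read is worth 2.997 to 6.81.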

Other observations

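The comparisons between organs and the values by sex were chosen after the data were seen; no test in this part was planned.

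Of the 51 genes lower in lung macrophages of depleted mice, 44 were measured in skin macrophages without the 2 libraries, a comparison with 1 control library. There 19 were lower and the median log2 fold change of the 44 was 0.32. S100a9 at −2.67, Retnlg at −2.34 and S100a8 at −1.80 were among the lower, whereas Slpi stood at 2.08 and Mmp8 at 1.67. The median standard error of a log2 fold change was 0.64 in lung macrophages and in lung fibroblasts, which lowers correlations across genes. Across genes, which are not independent replicates, the depletion effects in lung macrophages and in that skin macrophage comparison had a Pearson correlation of −0.0285 over 9936 genes. Those in lung and skin fibroblasts had one of 0.0276 over 9585 genes, and those in lung macrophages and lung fibroblasts one of 0.0367 over 11867 genes. The interferon list had 14 of 19 members lower in lung macrophages (median −0.46, adjusted p = 0.0587) and 14 of 19 higher in lung fibroblasts (median 0.38, adjusted p = 0.1701, and 0.15 with 4 genes at 0 reads in a group at their bounds); neither passed the test and the difference was not tested. Efferocytosis and LXR target genes, which macrophages use to clear dying neutrophils, had 11 of 19 members higher in lung macrophages with a median of 0.18 (adjusted p = 0.439).

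Xist and Ddx3y, transcripts of the inactive X and of the Y chromosome, split the skin libraries by replicate number. Libraries numbered 1 to 3 carried Xist and those numbered 4 and 5 carried Ddx3y, so each skin group holds both sexes, and the depleted and the control fibroblasts each hold 1 library with Xist and 2 with Ddx3y. In lung no library was assigned a sex.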
